A study of Mus musculus with 4 samples.

How the data were processed

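Expression was measured on 4 Agilent mouse arrays of 44397 spots, 1 array per RNA pool of 3 mice, with 2 pools from WT and 2 from STAP-2-/- colons. Per the labels' protocols, RNA of the entire colon was labelled with Cy3 together with spike-in controls. Per the file headers, the authors' deposited scanner files hold the processed signal intensity of each spot, background-subtracted and detrended within the array, and not normalized between arrays. Agilent Feature Extraction 10.7.1.1 made them, per the submitters' processing notes. The same deposited files hold the median spot intensity, the median local background intensity and flags per spot. The authors' deposited value table holds a ratio: it equals the processed signal divided by 1 constant per array, within 1% for 100% of the probes compared, with a 75th percentile of 1 and column medians of 0.090, 0.087, 0.091 and 0.084. Its scale is linear and it is not centred by gene; it was used as an alternative only.

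All 4 arrays lay on 1 slide and came from 1 scan, so no slide or scan could be tested as a batch. WT 1, STAP-2-/- 1, WT 2 and STAP-2-/- 2 held positions 1, 2, 3 and 4, so the number in the labels follows the position. No 2 arrays held identical values. Over 317 probes spotted several times, the median SD between spots of 1 array was 0.040 to 0.043 on the log2 scale, and the median SD between the arrays of a genotype was 0.131 for WT and 0.239 for STAP-2-/-. Each array was counted as a sample, as the labels list them. No spot was saturated, and between 129 and 190 spots per array were outlier-flagged.

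Values here are log2 of the processed signal minus its 75th percentile over non-control spots of the array. Control spots were left out, spots flagged as outliers were set missing, and spots of a probe were averaged. Of 39429 probes, 27427 were named through the accession of their target, matched without versions to a RefSeq table of assembly GRCm38.p6, giving 20832 genes; 12002 probes had no gene named and were not tested as genes. The array's own annotation uses another build, so the table served for names and neighbour order only and no coordinates are given. A gene with several probes (5494 genes) was represented by the probe with the highest mean. A gene was tested if its probe was well above background on both arrays of at least 1 genotype, which left 15560 genes. Where a gene was not well above background on either array of a genotype, only a bound of the fold is given, and none where the bound is under 1; the fitted log2 difference of Stap2 is given beside its bound for the test and its alternatives.

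Genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no covariate. All adjusted p-values of genes come from that model. Gene lists were tested with limma camera at a preset correlation of 0.01, adjusted over 54 lists with at least 5 tested members each. Of 1083 list symbols, 1080 were found in the table, 5 of them under an older name. Named genes follow a fixed rule: Stap2, then up to 12 per direction with the largest change past the threshold, with remaining places going to the smallest unadjusted p among genes at least 2-fold apart with no overlap between the groups. Up to 4 members with the smallest unadjusted p were added from each list that passed and from 9 lists the study's question concerns. Expressed-sequence, clone and receptor-segment names were left out, and 2 list members that the rule names are not reported here. A list member that did not pass the gene test is given by its values only.

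The gene fit and the list test were tested on simulated data: 20 draws of 4 arrays from the measured means and spreads of 15550 genes, with 200 changed genes. Genes given a 16-fold change passed in 70.1% of cases, and 1.7 unchanged genes were called per draw on average. In the 20 draws 0 of 1060 unshifted lists were called, with genes drawn independently of each other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and drawing.

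Alternatives, whose effect the closing section gives, were quantile and median scaling, the 75th percentile over probes above background on all arrays, the authors' value table, other filters on dim probes, flagged spots kept, the mean of the probes of a gene, an intensity trend with robust fit, a test against a 1.2-fold change, the replicate number as a block, an estimated correlation, fry, and leaving out each array. Normexp background correction with an offset of 50 was run on the median spot intensity, in place of the planned mean intensity; that choice was made after seeing the data.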

Results

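Whole colons were compared between wild-type (WT) mice and mice lacking STAP-2, an adaptor protein that binds STAT3, STAT5, MyD88 and the receptor Csf1r. All mice had drunk 1.75% dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium and starts an acute colitis. The labels give the length of DSS treatment as 3 days in one field and 7 days in another, so it is left open here. RNA was pooled from 3 mice aged 14 weeks for each sample and put on a 1-colour Agilent mouse array, giving 2 WT and 2 STAP-2-/- arrays. The question the design puts is which transcripts of the DSS-treated colon differ when STAP-2 is missing. The sample titles call the pools of a genotype biological replicates, and the labels give no further detail on the mice of each pool. The p-values of single genes measure the spread between these samples. Those of gene lists by camera with the preset correlation compare the genes of a list with the other genes. They take the spread over genes, so they do not measure the spread between these samples.

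The 75th percentile of the processed signal was 2134 and 2215 on the WT arrays and 2280 and 2348 on the STAP-2-/- arrays. Between 68.4% and 70.5% of the non-control spots lay well above background, and the number of arrays, 2 per genotype, limits the precision. Over 25625 probes well above background on all 4 arrays, the SD of log2 differences was 0.405 between the WT arrays and 0.603 between the STAP-2-/- arrays. Across genotypes it was 0.334 between both arrays numbered 1 and 0.361 between both arrays numbered 2, lower than within either genotype.

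**Figure D1:**
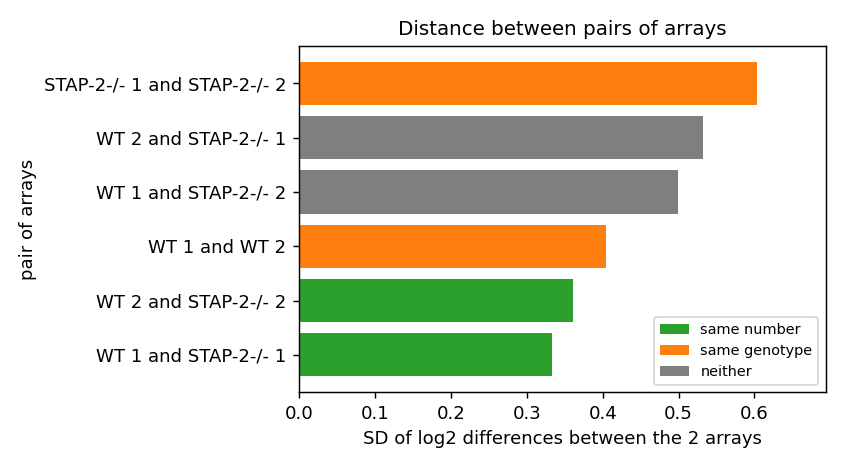
Each bar is a pair of arrays, and its length is the SD of log2 differences over 25625 probes well above background on all 4 arrays. The pairs with the same number in the labels have the shortest bars, 0.334 and 0.361, and the 2 STAP-2-/- arrays have the longest, 0.603.

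Stap2, the targeted gene on chromosome 17, gave a bright signal in WT colons and none well above background on either STAP-2-/- array. Its log2 value relative to the 75th percentile was 2.95 ± 0.046 (SD, n = 2) in WT and -7.18 ± 0.77 (SD, n = 2) in STAP-2-/- colons. WT was at least 721.9-fold higher, a bound that sets each STAP-2-/- array at the higher of its own signal and the lowest signal well above background there. All 4 arrays carried the Stap2 level that their genotype label calls for. The fitted log2 difference, which takes the STAP-2-/- signals as read and is no measure of the fold, was -10.13 (SE 0.41), with a limma adjusted p of 0.314. With normexp background correction the Stap2 level in STAP-2-/- against WT colons was -7.52, with an adjusted p of 0.00453, the lowest of a range up to 0.555 over the alternatives. The array holds 1 probe for Stap2, and its place relative to the deleted part was not analysed here.

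No gene passed the limma test at an adjusted p of 0.05 among 15560 genes tested, with 0 higher and 0 lower. An unadjusted p under 0.05 was found for 325 genes, 124 of them higher in STAP-2-/- colons and 201 lower. The split of the arrays by their numbers gave 3943 genes at that unadjusted p and the remaining split 110. Arrays were also simulated from the measured means and spreads with 15550 genes. There 33.9% of genes given a 4-fold change and 0.2% of those given a 2-fold change passed the adjusted p of 0.05. Among unchanged simulated genes 5.85% had an unadjusted p under 0.05, a larger share than the 325 genes make up. The simulated arrays were drawn independently, while deviations from the genotype means correlated by 0.596 between measured arrays of equal number. Differences between the numbers widen the spread within a genotype, so the count of 325 is no sign for or against a genotype effect. The section on processing gives the count with the number as a block. By size alone, 51 genes were at least 2-fold higher in STAP-2-/- colons with no overlap between the groups, and 72 were at least 2-fold lower. The split of the same arrays by their numbers gave 707 such genes in both directions together, against 123 for genotype and 57 for the remaining split. Leaving out 1 array loosens the no-overlap rule, and the genes over 2-fold apart with no overlap between groups were then 104 (without WT 2) to 256 (without STAP-2-/- 2) higher in STAP-2-/- and 124 (without WT 2) to 285 (without STAP-2-/- 1) lower in STAP-2-/-. Over all sizes, 24.9% of tested genes had no overlap between the genotypes, where chance gives 33.3%; the share was 62.4% for the split by number and 12.8% for the remaining split, and the 3 shares make up all genes.

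Of the 109 genes other than Stap2 that the naming rule gave, 59 had a log2 difference that moved by over 1.5 times when 1 array was left out, 44 of them without STAP-2-/- 2. The genes named next are those of the size rule with the smallest unadjusted p, and none is past the adjusted threshold. Of those lower in STAP-2-/- colons, 8 were well above background on all 4 arrays. Socs3, the feedback inhibitor that STAT3 induces, was 2.54-fold lower, at 1.02 ± 0.074 against 2.36 ± 0.39 in WT (log2, SD, n = 2). Scd1, the stearoyl-CoA desaturase, was 2.14-fold lower. Clca4b, of the chloride channel accessory family, was 2.79-fold lower, the amino acid transporter Slc36a2 2.30-fold lower and the secreted protein Crisp3 3.53-fold lower. The homeobox gene Evx1 was 2.66-fold lower, the non-coding RNA Mirg 2.60-fold lower and the calpain family gene Capn6 2.55-fold lower. The odorant receptor genes Olfr705, Olfr5 and Olfr706 and the embryonic myosin gene Myh3 were not well above background on either STAP-2-/- array, and WT was at least 2.45-, 1.82-, 1.71- and 1.41-fold higher.

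On the higher side, Cd6, a surface receptor of T cells, was 2.59-fold higher in STAP-2-/- colons, at -2.11 ± 0.26 against -3.48 ± 0.29 (log2, SD, n = 2), and the synaptotagmin gene Syt8 was 3.14-fold higher. Hbb-bh1, an embryonic globin gene, was 5.20-fold higher and well above background on 1 of the 2 WT arrays. The other 9 of the 12 named genes were not well above background on either WT array, so only bounds are given. STAP-2-/- colons were at least 4.85-fold higher for the lens crystallin gene Crygf, at least 2.02-fold for the hair keratin-associated gene Krtap9-3, at least 1.76-fold for Speer4b and at least 1.57-fold for Slc5a4b. For Olfr1093, Frs3os, Pramel51 and Olfr1389 the bounds were 1.55-, 1.43-, 1.33- and 1.01-fold, and for Tmem45a2 no bound above 1 could be given.

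**Figure D2:**
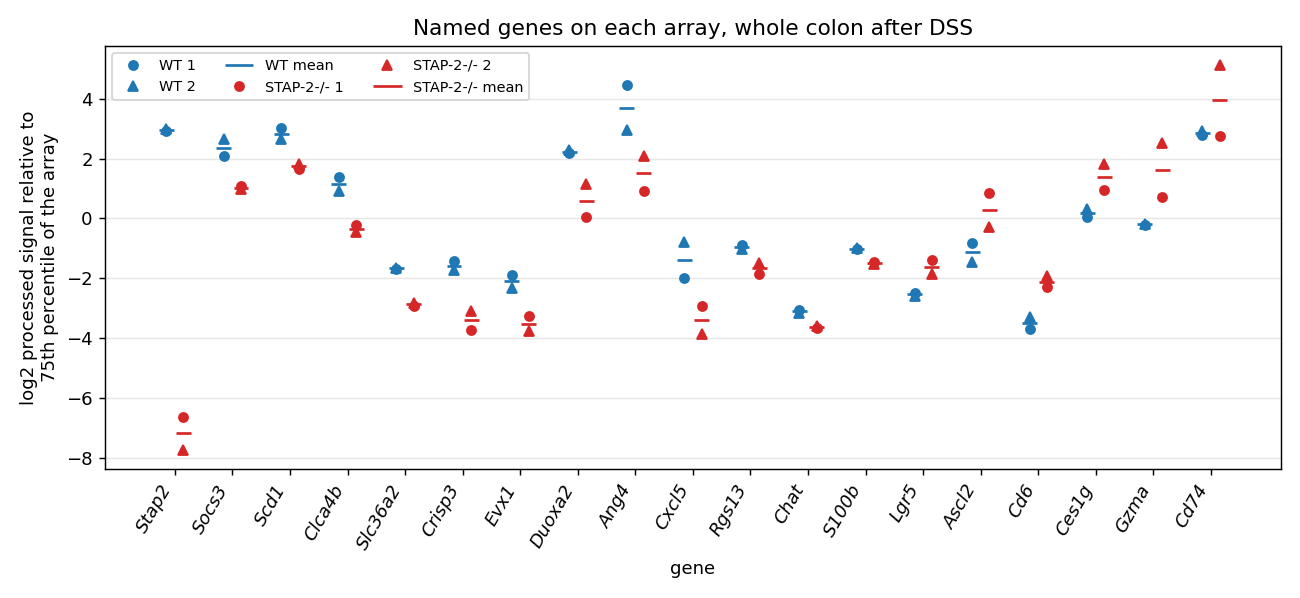
Points are the log2 processed signal of 19 named genes on each array, relative to the 75th percentile of that array, with circles for arrays numbered 1, triangles for arrays numbered 2 and short lines for the group means (n = 2). Stap2 stands at 2.95 in WT and -7.18 in STAP-2-/-, Socs3 and Scd1 separate cleanly between the genotypes, and Cd74 is high on 1 STAP-2-/- array.

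Of 54 gene lists, 7 rose and 12 fell in STAP-2-/- colons by limma camera with its preset correlation of 0.01. Some lists share genes, so their calls are not fully separate results. Alox5 is in the tuft cell and the prostaglandin lists, and Reg3b and Reg3g are in the antimicrobial and the STAT3 lists. Nos2 is in the antimicrobial and the NF-kB lists, and Tnf in the NF-kB and the cytokine lists. No member of any list passed the gene test, either over all genes or adjusted over the list alone. None of the 19 lists held with an estimated correlation, and none passed fry, whose adjusted p was 0.99 for each. With 2 arrays per genotype each of these also called a list shifted by 0.4 in 0 of 20 simulated draws, where the preset correlation called it in 16. Those draws took genes independently of each other, a setting that favours the preset value, so they do not show that the preset calls are sound. On the measured arrays the estimated correlation of the 19 lists ran from -0.036 (smooth muscle) to 0.88 (interferon-gamma and GBP genes), with 0.83 for type I interferon genes. Splitting the arrays by number called 14 lists with the preset correlation, and the remaining split called 12. Lists that rose numbered 3 without STAP-2-/- 2 and 12 without WT 2, and lists that fell 6 without WT 2 and 15 without WT 1. Enteric neurons and glia was the 1 list of the 19 that stayed called whichever array was left out.

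**Figure D3:**
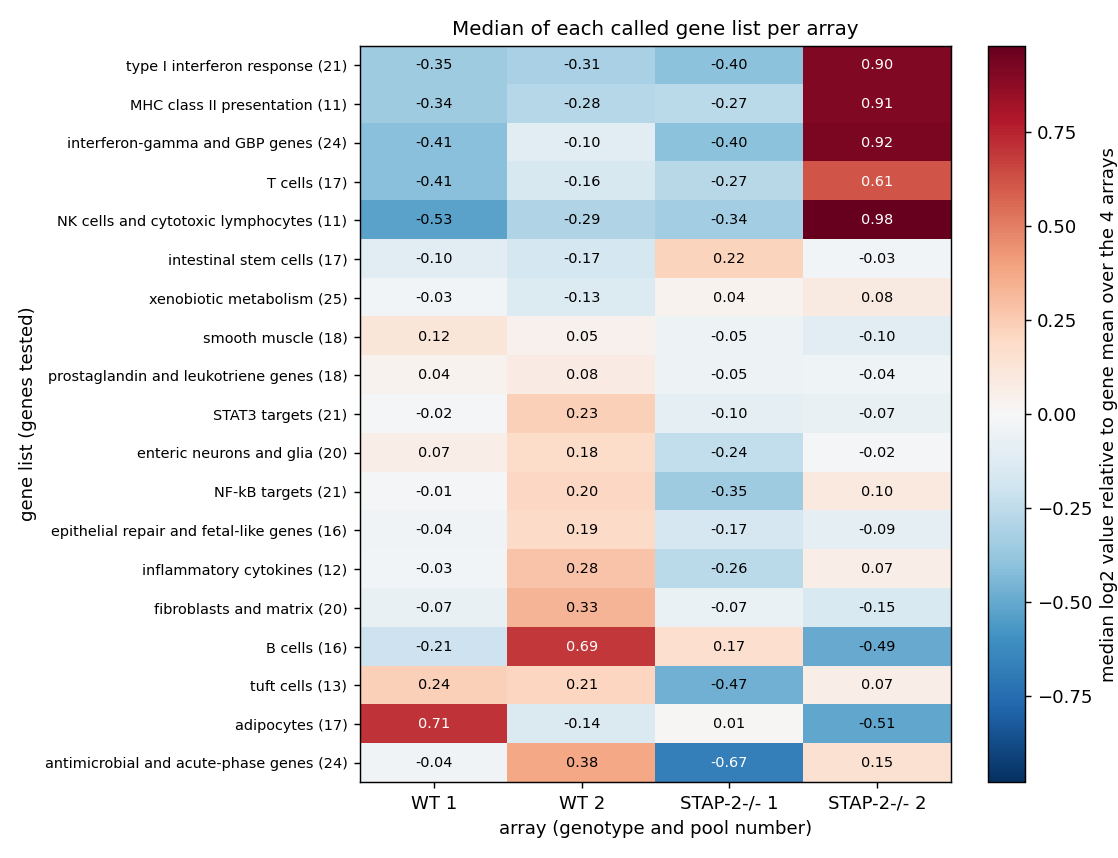
Each cell is the median over a list's tested genes of the log2 value relative to the gene's mean over the 4 arrays, for the 19 lists called by limma camera, with the number of genes in parentheses. Type I interferon genes sit at 0.90 on STAP-2-/- 2 and between -0.40 and -0.31 on the other 3 arrays, while enteric neuron and glia genes are lower on both STAP-2-/- arrays than on both WT arrays.

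Markers of the nerves and muscle of the gut wall fell in STAP-2-/- colons. All 20 enteric neuron and glia genes were lower, 11 of them with no overlap, with a median log2 difference of -0.25 and a camera adjusted p of 9.33e-08 (adjusted p = 0.689 with an estimated correlation). Chat, which makes acetylcholine, differed by -0.52 (SE 0.13), the glial gene S100b by -0.47 (SE 0.13) and the synaptic gene Syt1 by -0.38 (SE 0.15). Of 18 smooth muscle genes, 17 were lower, with a median of -0.16 and adjusted p = 0.000556 (adjusted p = 0.689 with an estimated correlation). The contractile genes Cnn1, Actg2 and Tpm2 differed by -0.32, -0.26 and -0.21, and the intermediate filament gene Synm by -0.44. The smooth muscle call ended without WT 1 (median -0.096). The neuron and glia median was -0.38 without STAP-2-/- 2 and -0.19 without STAP-2-/- 1. Against WT 1 and WT 2 that list's median difference was -0.38 and -0.44 for STAP-2-/- 1, and -0.11 and -0.22 for STAP-2-/- 2, so the fall was larger in the first pool.

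Connective and fat tissue genes were lower as well. In the fibroblast and matrix list 19 of 20 genes were lower, with a median of -0.30 and adjusted p = 0.000384. Dpt differed by -0.31, Lum by -0.48 and Sparc by -0.44, while Thy1, also a T cell marker, was the 1 member that was higher (0.24). Of 17 adipocyte genes, 14 were lower, with a median of -0.55 and adjusted p = 4.42e-06. Scd1 differed by -1.10, Adig by -0.94, the adipokine Retn by -0.99 and Cidea by -0.40. Both lists had adjusted p = 0.709 with an estimated correlation. The fibroblast call ended without WT 2 (median -0.054, adjusted p = 0.717) and without STAP-2-/- 2 (0.131). The adipocyte call ended without WT 1 (median -0.16, adjusted p = 0.192), the array with the most adipocyte signal, and without STAP-2-/- 2 (median -0.21, adjusted p = 0.0740), and its median was -0.97 without WT 2.

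In the epithelium, tuft cell genes fell and intestinal stem cell genes rose. Of 13 tuft cell genes, 11 were lower, with a median of -0.44 and adjusted p = 2.20e-06. Gnat3, the taste G protein, differed by -0.83 (SE 0.20), Rgs13 by -0.71 (SE 0.19), Hmx2 by -0.67 (SE 0.16) and the leukotriene enzyme Alox5 by -0.53 (SE 0.19). Of 17 stem cell genes, 15 were higher, 8 with no overlap, with a median of 0.18 and adjusted p = 2.85e-05. Lgr5, the receptor that marks crypt base stem cells, was 1.87-fold higher and the stem cell transcription factor Ascl2 2.66-fold higher. Axin2, a Wnt target, differed by 0.57 (SE 0.27) and Cdca7 by 0.37 (SE 0.13). Both lists had adjusted p = 0.689 with an estimated correlation. Without STAP-2-/- 1 the tuft cell median was -0.17 (adjusted p = 0.206) and the stem cell median 0.15 (adjusted p = 0.0630), and without STAP-2-/- 2 they were -0.73 and 0.40.

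Genes of xenobiotic metabolism also rose, 18 of 25 members being higher, with a median of 0.13 and adjusted p = 0.0199 (adjusted p = 0.689 with an estimated correlation). The carboxylesterase Ces1g was 2.29-fold higher, the sulfotransferase Sult1a1 1.47-fold, Cyp3a13 1.37-fold and the retinal dehydrogenase Aldh1a1 1.34-fold. The call ended without WT 2 (median 0.13), without STAP-2-/- 2 (median 0.16) and with the replicate number as a block. Epithelial repair genes fell, 15 of 16 being lower, with a median of -0.28 and adjusted p = 0.0199 (adjusted p = 0.689 with an estimated correlation). The growth factor Areg differed by -0.47 (SE 0.15), Anxa1 by -0.48 (SE 0.23) and the alarmin Il33 by -0.31. That call was lost with no filter on dim probes (adjusted p = 0.0648), held without WT 1 and was lost without any other array, with a median of -0.012 and adjusted p = 0.573 without WT 2 and a median of -0.17 and adjusted p = 0.197 without STAP-2-/- 1.

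Antimicrobial and inflammatory genes fell. In the antimicrobial and acute-phase list 21 of 24 genes were lower, with a median of -0.68 and adjusted p = 0.000101. Ang4, an antimicrobial ribonuclease, was 4.57-fold lower and Duoxa2, the maturation factor of the oxidase Duox2, 3.11-fold lower. The plasma protein gene Orm1 was 2.22-fold lower and the cathelicidin gene Camp 1.43-fold lower. With 1 array left out, the log2 difference of Ang4 ran from -2.95 to -1.43 and that of Orm1 from -1.59 to -0.71. Of 21 NF-kB targets, 20 were lower, with a median of -0.25 and adjusted p = 0.00158. Nos2, the inducible nitric oxide synthase, differed by -1.79 (SE 0.89), Ier3 by -0.56, the RNase Zc3h12a by -0.47 and Bcl3 by -0.35; without WT 1, Nos2 differed by -0.82. Of 12 inflammatory cytokine genes, 10 were lower, with a median of -0.29 and adjusted p = 0.0159. Il22 differed by -1.67 (SE 0.86), Tnf by -1.34 (SE 0.75), Il33 by -0.31 and Lif by -0.28. Without WT 2, Il22 differed by -0.63 and Il33 by -0.0039, and without STAP-2-/- 1, Tnf differed by -0.33 and Lif by -0.043. All 3 lists had adjusted p = 0.689 with an estimated correlation. Without WT 2 their medians were -0.0028, -0.061 and -0.13, and adjusted p was 0.123, 0.123 and 0.305. The NF-kB and cytokine calls ended without STAP-2-/- 1 as well (medians -0.13 and -0.093, adjusted p = 0.604 and 0.628), where the antimicrobial median was -0.20. Without STAP-2-/- 2 the NF-kB and cytokine medians were -0.43 and -0.46, and without WT 1 the cytokine median was -0.50.

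Targets of STAT3, a partner of STAP-2, fell by a median of 0.23, with 15 of 21 members lower and adjusted p = 0.0376 (adjusted p = 0.689 with an estimated correlation). Socs3 differed by -1.34 (SE 0.24), the lipopolysaccharide-binding protein Lbp by -0.80 (SE 0.40), the oncostatin M receptor Osmr by -0.64 (SE 0.40) and Bcl3 by -0.35 (SE 0.16). With 1 array left out, Socs3 ran from -1.62 to -1.07, Lbp from -1.33 to -0.27, Osmr from -1.08 to -0.19 and Bcl3 from -0.48 to -0.21. The list was called without WT 1 and lost without any other array, with a median of -0.090 and adjusted p = 0.704 without WT 2, and with no filter on dim probes adjusted p was 0.0545. Prostaglandin and leukotriene genes fell, 13 of 18 being lower, with a median of -0.22 and adjusted p = 0.0378 (adjusted p = 0.689 with an estimated correlation). Ptgds, a prostaglandin D2 synthase, differed by -0.60 (SE 0.20), Alox5 by -0.53 and the receptor gene Ptger3 by -0.35, while Alox15, not well above background on WT 1, was higher by 0.59. This call ended without WT 2 (0.148) and without STAP-2-/- 1 (median -0.092, adjusted p = 0.699), with the mean of the probes of a gene (median -0.14, adjusted p = 0.104) and with no filter on dim probes (0.0907).

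Lymphocyte, interferon and antigen presentation genes rose in the genotype test, and the medians were high on the STAP-2-/- 2 array. All 17 T cell genes were higher, with a median of 0.42 and adjusted p = 3.10e-07 (adjusted p = 0.689 with an estimated correlation). All 21 type I interferon genes were higher, with a median of 0.58 and adjusted p = 1.70e-06 (adjusted p = 0.765 with an estimated correlation). For interferon-gamma and GBP genes 20 of 24 were higher, with a median of 0.52 and adjusted p = 0.000206 (adjusted p = 0.873 with an estimated correlation). Of 11 NK cell and cytotoxic genes, 10 were higher (median 0.35, adjusted p = 0.00158), and so were 9 of 11 MHC class II genes (median 0.57, adjusted p = 0.00794), both with adjusted p = 0.689 with an estimated correlation. Without STAP-2-/- 2 the medians of these 5 lists were 0.11, -0.057, -0.13, 0.18 and 0.13, and adjusted p was 0.230, 0.680, 0.203, 0.247 and 0.644. Without STAP-2-/- 1 the medians were 0.74, 1.17, 1.23, 1.153 and 1.19, and without WT 2 the NK cell median was 0.74. The MHC class II call also ended without WT 1 (0.126).

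Members of these lists are named by their smallest unadjusted p, which favours genes set apart in both pools. Of the 20 named here, all but Cd74 were higher on both STAP-2-/- arrays than on both WT arrays, while over the whole lists that held for 5 of 17 T cell, 7 of 21 type I interferon, 5 of 24 interferon-gamma, 4 of 11 NK cell and 4 of 11 MHC class II genes. Cd6 and Thy1 stood at like levels in both pools, as did Prf1, which makes perforin, at -2.72 on STAP-2-/- 1 and -2.76 on STAP-2-/- 2 against -2.86 and -2.94 in WT. Others stood far higher on STAP-2-/- 2. The granzyme gene Gzmb stood at 0.63 there and at -2.27 on STAP-2-/- 1, against -2.79 and -2.44 in WT, and Gzma at 2.50 and 0.71 against -0.21 and -0.17. Oas3, a sensor of double-stranded RNA, stood at -1.64 and -4.29 against -4.81 and -4.78, and H2-Ab1 at 5.41 and 4.08 against a WT mean of 3.94. Cd74, the MHC class II invariant chain, stood at 5.12 and 2.76 against 2.79 and 2.92. H2-DMa, H2-Aa, Cd8a and Cd3e differed by 1.12, 0.88, 1.51 and 0.42 between the genotypes, and by 0.28, 0.24, 0.32 and 0.25 without STAP-2-/- 2. For Irf7, Dhx58 and Trim30a these values were 0.77, 0.58 and 0.59, and 0.23, 0.18 and 0.26. Tap1, Gbp2, Psmb9 and Psmb8 differed by 0.88, 0.93, 0.83 and 0.83, and the chemokine gene Ccl5 by 1.28, and without that array by 0.58, 0.48, 0.30, 0.24 and 0.30.

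B cell genes went the other way: 14 of 16 were lower, with a median of -0.32 and adjusted p = 0.0378 (adjusted p = 0.873 with an estimated correlation). Spib differed by -0.43, the follicle homing receptor Cxcr5 by -1.01, Fcer2a by -0.70 and Ebf1 by -0.26. With 1 array left out, Spib ran from -0.65 to -0.20, Cxcr5 from -1.54 to -0.48, Fcer2a from -1.36 to -0.031 and Ebf1 from -0.49 to -0.022. The list stood highest on WT 2, at 0.69 relative to the gene means, and lowest on STAP-2-/- 2, at -0.49. Without WT 2 the median was 0.0048 (adjusted p = 0.704), and without STAP-2-/- 2 it was 0.051 (adjusted p = 0.872); it was -0.84 without WT 1 and -0.67 without STAP-2-/- 1. With no filter on dim probes adjusted p was 0.0990, and with the replicate number as a block the list was not called.

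Macrophage, chemokine and STAP-2 partner genes, which the question also concerns, did not pass the list test of the model without a block on all 4 arrays. The 20 macrophage and monocyte genes had a median of 0.044 and adjusted p = 0.435. The complement genes C1qb, C1qa and C1qc, made by macrophages, differed by 0.28, 0.25 and 0.25, and Lilrb4a by -0.35 (SE 0.50); without STAP-2-/- 1 the list was called, with a median of 0.27 (adjusted p = 0.00651). Of 22 chemokine genes 17 were lower, with a median of -0.24 and adjusted p = 0.0805, and the list was called without STAP-2-/- 2 (median -0.57, adjusted p = 0.00355) and without WT 1 (median -0.50, adjusted p = 6.99e-08). Cxcl5, a neutrophil attractant, was 3.98-fold lower with no overlap between the groups, Ccl17 differed by -0.65 and Ccl19 by -0.91, while Ccl5 was higher by 1.28. With 1 array left out, Ccl17 ran from -1.01 to -0.29, Ccl19 from -1.63 to -0.18 and Ccl5 from 0.30 to 2.25. In the same way C1qb ran from 0.15 to 0.40, C1qa from 0.035 to 0.46 and C1qc from 0.024 to 0.47, each lowest without STAP-2-/- 2. The 16 chemokine receptor genes had a median of 0.12 (adjusted p = 0.490), with Ccr9 at 0.55, Ccr10 at 0.24, Ccr7 at -0.54 and Cxcr5 at -1.01; it was called without WT 2 (median 0.20, adjusted p = 0.00774) and without STAP-2-/- 1 (median 0.19, adjusted p = 0.0421). For 21 genes of STAP-2 partners and signalling the median was -0.067 (adjusted p = 0.478). The kinase genes Ptk6 and Ptk2b differed by -0.65 and 0.19, and Stat3 and Stat5a by -0.22 and -0.15. With 1 array left out, Ptk6 ran from -1.08 to -0.22 and Stat3 from -0.34 to -0.090.

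Genes near Stap2 on chromosome 17, listed because a targeted locus can carry flanking sequence of another strain, did not move together. The 27 tested genes, 26 of them on that chromosome, had a median of 0.031, a mean of -0.051 and adjusted p = 0.767, so the median and the mean differ in sign. The list test looks for a shared direction, so it cannot decide whether single neighbours changed in either direction. Shd differed by -0.68 (SE 0.15), Plin5 by -0.62 (SE 0.18), Yju2 by 0.34 (SE 0.13) and Safb by 0.23 (SE 0.16).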

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

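Of the tests in this part, the spike-in test was written before its result was seen; the count of unnamed probes, the single-pool test, the B cell test, the count of lists per pool, the clock gene test, the colitis test and the gut wall test were chosen only after the result was seen.

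Among 12002 probes with no gene named, 75 were well above background on both STAP-2-/- arrays and neither WT array, against 18 the other way. The comparisons of the report do not use these probes. Among 27427 probes with a gene named the same counts were 96 and 38. More non-control spots were well above background on both STAP-2-/- arrays (69.8% and 70.5%) than on both WT arrays (68.4% and 69.7%). The difference in the probe counts was not tested.

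Interferon, MHC class II, T cell and NK cell genes were higher in STAP-2-/- colons, by list medians high on 1 of the 2 pools. Over the 84 genes of the 5 lists, STAP-2-/- 1 differed from the mean of the WT arrays by a median of 0.01403 (SE over genes 0.0561) and STAP-2-/- 2 by 1.188 (SE over genes 0.0844); the lists were put together after this was seen, so it restates that STAP-2-/- 2 stood apart. Lymphoid follicles carried along in that pool would bring B cell genes. These were lower there than on the other 3 arrays, with a median difference of -0.6526 (SE over genes 0.259), which gives no sign of follicles. The test was chosen after the low B cell level of that pool was seen and rests on 1 pool. Its SE takes the genes as independent, so it does not settle the source. An effect of the genotype present in both pools stays open, since the median of gene-by-gene differences put STAP-2-/- 1 above both WT arrays for 1 of the 5 lists and below both for 2. With 2 pools per genotype, 1 divergent pool and a genotype effect of uneven size were not separated.

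The arrays were alike by replicate number more than by genotype. Handling, time of day and the stage of colitis were looked at as sources. Others were not tested, although Hoxd13, Myh8, Myh2 and the Y-linked genes Eif2s3y and Ddx3y were also lower in number 2 in both genotypes. The number split gave 707 genes at least 2-fold apart with no overlap against 123 for genotype, and the number follows the position on the slide. Labelling, hybridization or slide position stays open. Around their own mean shift, 7 spike-in probes varied between the numbers 0.2715 times as much (SE 0.0928) as genes of like brightness. That ratio lies between the bounds set for and against this explanation. The mean shift itself, number 2 minus number 1, was 0.3235 (log2), and the ratio leaves it out. Different time of day at collection is a candidate explanation, as clock genes of opposite phase moved apart by 3.092 in WT and 1.866 in STAP-2-/- colons (log2). So is a different stage or strength of colitis. The medians of 6 of 6 inflammatory, remodelling and cell cycle lists moved the same way between the numbers in both genotypes. Sizes ran from 0.105 (neutrophils, STAP-2-/-) to 1.154 (cell cycle, WT), and the neutrophil median moved by 0.996 in WT. The clock gene and colitis tests were chosen after the result was seen, so they restate the pattern and are no independent support.

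Enteric neuron and glia, smooth muscle and fibroblast genes were lower in STAP-2-/- colons, and a smaller share of the outer gut wall in that tissue would lower other wall cells too. Of 4 wall lists compared, only endothelium lies outside the pattern, and its medians of 1 STAP-2-/- array against 1 WT array ran from -0.176 (SE over genes 0.127) to 0.02016 (SE over genes 0.0760). They decide nothing, so an effect of the genotype on these cells and a smaller share of the wall cannot be told apart.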

How the results depend on the processing

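Normexp correction was chosen only after the result was seen; the other alternatives, the model, the lists and the naming rule were fixed before the data were examined. Quantile and median scaling, the other percentile, the authors' value table, outlier spots kept, the intensity trend and the 1.2-fold test gave 0 genes, as limma did (325 at unadjusted p under 0.05), and the 4 other scalings called the same 19 lists; 18 of them were called with the mean of the probes (prostaglandin and leukotriene genes lost, adjusted p = 0.104) and 15 with no filter (those genes at 0.0907, epithelial repair 0.0648, STAT3 targets 0.0545, B cells 0.0990). With normexp the Stap2 level was -7.52 (adjusted p = 0.00453; 0.00453 to 0.555 over all alternatives), 1 gene was lower, 16 and 26 genes were at least 2-fold higher and lower with no overlap, and the median beside Stap2 on chromosome 17 was -0.0020; the cause was not tested. Those 2-fold counts were 139 and 199 with no filter on dim probes, where more genes were tested, and 25 and 44 with the filter on all 4 arrays, which leaves out Stap2 and so gives no value for it. An estimated correlation called 0 lists higher and 0 lower and fry 0 and 0. Each also called a list shifted by 0.4 in 0 of 20 simulated draws, which took genes independently and so cannot back the preset calls.

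Leaving out each array, with the lone array assumed to vary like the other group, gave 104 to 256 genes at least 2-fold higher and 124 to 285 lower, fewer samples making overlap rarer, 3 to 12 lists higher and 6 to 15 lower. The medians of lists that turned sign ran from -0.057 to 1.17 for type I interferon, -0.13 to 1.23 for interferon-gamma and GBP genes, -0.84 to 0.051 for B cells, -0.19 to 0.27 for macrophages, -0.57 to 0.043 for chemokines, -0.13 to 0.20 for chemokine receptors, -0.11 to 0.0048 for STAP-2 partners and -0.081 to 0.0014 for genes beside Stap2. Cd74 ran from -0.091 to 2.27 and Lilrb4a from -0.95 to 0.25; fewer samples are left by construction, and the cause beyond that was not tested. The fitted Stap2 difference, no measure of the fold, ran from -10.67 to -9.58 (adjusted p 0.0528 to 0.490).

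With the replicate block, 0 genes were called in either direction (1040 at unadjusted p under 0.05), 8 lists were higher and 12 lower, 17 of them among the 19 (xenobiotic metabolism at 0.0766 and B cells at 0.232 were not called, chemokines at 0.0455 were), and Stap2 had an adjusted p of 0.555; deviations from the genotype means correlated by 0.596 between equal numbers, and the labels give no shared batch for the numbers. A slide or scan block was not run, as there is 1 slide and 1 scan. Signal over background limits genes that are dim in 1 genotype, Stap2 among them, to bounds of the fold.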

Other observations

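The comparison of replicate numbers and its genes were chosen only after the result was seen; the gene lists were not.

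In both genotypes, the colons numbered 2 differed from those numbered 1 by many genes. Of 15145 genes well above background on all 4 arrays, 142 were over 2-fold higher and 106 over 2-fold lower in number 2 in both genotypes, and 19 went in opposite directions. The antimicrobial lectin Reg3g was higher by 2.83 in WT and 3.67 in STAP-2-/- colons (log2), and Reg3b by 2.36 and 3.09. The formyl peptide receptor gene Fpr1 was higher by 2.73 and 2.75, the calprotectin gene S100a9 by 5.10 and 2.41, and the interleukin-33 receptor gene Il1rl1 by 2.33 and 2.18. Genes of matrix-degrading enzymes were higher, Mmp10 by 3.28 and 2.23, Mmp13 by 2.33 and 2.25 and Adamts4 by 2.93 and 2.39, as was the chemokine gene Ccl4 by 2.14 and 2.48.

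As lists, with the preset correlation, cell cycle genes rose by a median of 1.01 (adjusted p = 4.83e-16; 0.728 with an estimated correlation), interferon-gamma and GBP genes by 0.80 (1.28e-05; 0.764), chemokines by 0.68 (0.000125; 0.728) and metalloproteinases and matrix genes by 0.60 (0.000428; 0.728). Of the 14 lists called, type I interferon genes rose by 0.58 (0.00357; 0.766), antimicrobial genes by 0.63 (0.00598; 0.766), T cell genes by 0.65 (0.0125; 0.766), dendritic cell genes by 0.36 (0.0125; 0.728), NF-kB targets by 0.32 (0.0152; 0.766), chemokine receptors by 0.32 (0.0152; 0.728) and macrophage genes by 0.29 (0.0152; 0.728), while ribosomal protein genes fell by 0.17 (0.0376; 0.766). Red cell genes fell by 0.68 and adipocyte genes by 0.61 (adjusted p = 0.00486 for both; 0.728 and 0.766 with an estimated correlation). These list tests took both genotypes together. Relative to the gene means, type I interferon genes had medians of -0.35 on WT 1, -0.31 on WT 2, -0.40 on STAP-2-/- 1 and 0.90 on STAP-2-/- 2. In the same order interferon-gamma and GBP genes stood at -0.41, -0.10, -0.40 and 0.92, and T cell genes at -0.41, -0.16, -0.27 and 0.61. The type I interferon rise thus lay on STAP-2-/- 2 alone. Lower in number 2 were Timp4, an inhibitor of metalloproteinases, at -1.98 and -2.15, and the clock gene Per3 at -2.78 and -2.25. The posterior homeobox gene Hoxd13 was lower as well, at -2.62 and -7.24. So were the skeletal muscle myosin genes Myh8, at -2.14 and -3.55, and Myh2, at -1.97 and -3.75, the defensin gene Defb45, at -2.35 and -5.96, and the cytochrome gene Cyp2c39, at -2.07 and -3.86. The 17 clock genes had a median of -0.84 and adjusted p = 0.125. Skeletal muscle genes (-0.38, adjusted p = 0.122), neutrophil genes (0.58, 0.102) and inflammatory cytokine genes (0.44, 0.0563) did not pass either.

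Transcripts of the sex chromosomes were well above background on all 4 arrays, and the labels used here give no sex. On WT 1, WT 2, STAP-2-/- 1 and STAP-2-/- 2, Xist, of the inactive X, stood at -2.51, -1.50, -1.60 and -2.48 (log2 relative to the 75th percentile). The Y-linked genes Eif2s3y and Ddx3y stood at 1.32, -0.66, 1.04 and 0.29, and at -0.13, -1.88, -0.64 and -0.90.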
